A study of Oncorhynchus mykiss with 12 samples.

How the data were processed

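Dorsal skin of wild-type and yellow mutant rainbow trout (Oncorhynchus mykiss) was profiled by RNA-Seq and by miRNA-Seq. The labels place 3 samples of each genotype in each assay, 12 samples in all, and the series text describes both genotypes as F1 offspring of wild-type males crossed with yellow mutant females. Per the labels' protocols, samples were flash-frozen in liquid nitrogen, total RNA was extracted with Trizol and libraries followed standard Illumina protocols. The labels do not state whether each sample is a separate fish or a pool, so every p-value measures only the spread between these samples.

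The RNA-Seq table holds FPKM values (fragments scaled to transcript length and to mapped fragments) for 6 libraries, made by the authors, per the file headers. The same table holds the authors' group means, their log2 fold change (per the file headers, yellow mutant mean over wild-type mean) and an FDR, that is, an adjusted p-value whose test is not stated in the sources used here. The miRNA-Seq table holds RPM values (reads scaled to a total of reads per library), given the heading TPM by the authors, with the authors' deposited log2 fold change and p-value. TopHat2 2.1.1 and Bowtie2 2.2.8 are listed per the submitters' processing notes, with no role given. The genome build, the counting tool and the miRNA caller and database are not given in the sources used here.

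The RNA-Seq table had 42290 entries, of which 41894 carried an NCBI gene identifier and 396 an identifier for an assembled transcript. All 41894 identifiers matched the RefSeq gene table of assembly USDA_OmykA_1.1, which was used for names only. Many trout genes have near-identical copies that arose by genome duplication. How reads shared by copies were assigned is not stated, so values of single copies are uncertain. The miRNA table had 1279 entries, 455 with a known family name and 824 predicted. Of these, 420 entries shared 173 sequences with another entry. The endings x, y and z of the miRNA names are given as the file gives them and their meaning is not stated.

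Library depth was read from the low values. Of the low values in the miRNA table, 100% were whole multiples of the value of 1 read, within a tolerance of 0.1 read, and an entry without reads is written as 0.01, which was set to 0. These steps gave denominators of 9095320 to 11502061 reads, so 1 read was worth 0.0869 to 0.110 RPM and a floor of 3 reads was worth 0.261 to 0.330. In every library the reads summed over the miRNA entries slightly exceeded the denominator (10524191 against 10405702 in wild-type replicate 1). The denominator is thus close to the reads counted in these entries and need not be all reads of a library. The floors cover counting error only. For FPKM, absolute depth is unknown. Depth relative to wild-type replicate 1 was estimated from the steps of low values between 0.02 and 0.3 FPKM, and on simulated values this estimate was off by at most 0.207%.

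Before the data were examined, the 2 comparisons, their tests, the 30 gene lists, the 8 miRNA family lists, the rule for named genes and most alternatives were fixed. Genes were tested when FPKM was at least 0.5 in at least 3 of the 6 samples, and miRNAs when the value was at least 1 in at least 3. The test was limma 3.58.1 in R 4.3.3, two-sided, on log2(value + 1) with eBayes set to trend and robust, genotype as the only term, and Benjamini-Hochberg adjustment at 0.05 over all entries tested. A fold change from this fit is on the log2(value + 1) scale, which understates the change of low genes. The smallest two-sided p of an exact permutation test of 3 samples against 3 is 0.1, so no such test was used for calls. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Each list was also tested with an estimated correlation and with fry, whose directional p asks whether the genes of a list move, on balance, one way and whose mixed p asks whether they change in either direction. Neither fry p compares a list with other genes. Within a list, limma's p-values were also adjusted over the list alone.

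The named genes are the 12 largest changes per direction past the threshold, with no overlap between genotypes, a mean of at least 1 FPKM in the higher genotype and an informative name. Where fewer passed, the smallest p-values filled the places. From each gene list the members past the threshold (at most 4) or else the member with the smallest p were added, and every measured copy of a set of pigment genes. For miRNAs the rule takes 8 per direction with a mean of at least 10 RPM, and the most abundant member of each family list.

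On simulated data built from the RNA-Seq values (27268 genes, 100 shifted by 1 and 100 by 2 on the log2 scale), the limma procedure recovered 68% of the smaller and 96% of the larger shifts, with 9 false calls. On simulated miRNA values (519 entries, 100 shifted by each size) it recovered 68% and 98%, with 5 false calls. In the simulated list test a shifted list was called and 0 other lists were, and with no change at all 1 of the 30 gene lists and 0 of the 8 family lists passed. Simulated values were drawn independently for each gene and sample. These counts therefore say nothing on false calls where the genes of a list move together.

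Alternatives were other pseudocounts (0.1 and 0.01), other filters (none, at least 5 FPKM, at least 10 RPM), quantile normalization, median-of-ratios scaling, eBayes without trend or robust, a fold threshold of 1 on the log2 scale with adjusted or unadjusted p, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were log2 relative depth as a covariate, 1 entry per distinct miRNA sequence, voom on the recovered miRNA reads, the block with an estimated correlation, and the other pseudocount and scaling for the miRNA family lists. Not run were a test of miRNA seed sites, since no transcript sequences were at hand, and a count model on the miRNA reads. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.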

Results

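Dorsal skin was compared between wild-type and yellow mutant trout of the same F1 cross, with 3 RNA-Seq and 3 miRNA-Seq samples per genotype. The yellow mutant is a colour form of rainbow trout, and the series title gives skin colour variation and a network of miRNAs and competing RNAs as its subject. The RNA-Seq columns summed to 396278 to 428561 FPKM, with 34837 to 35705 genes above 0 per library. Relative to wild-type replicate 1, estimated depth was 0.943 and 0.901 in wild-type replicates 2 and 3, and 1.01, 0.582 and 0.812 in yellow mutant replicates 1, 2 and 3. The denominators of the miRNA libraries were 10405702, 9162872 and 9552748 reads in wild-type skin and 11502061, 9095320 and 9706409 reads in yellow mutant skin, in the order of their numbers. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.937 to 0.966 within a genotype and 0.932 to 0.965 between genotypes for RNA-Seq. For miRNA-Seq they were 0.977 to 0.987 within and 0.974 to 0.988 between genotypes.

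The first comparison asks which genes differ in expression between the skins of the 2 colour forms. Yellow mutant skin had higher transcript levels of some genes for pteridine pigment synthesis, for melanin and melanosomes, and for a melanocortin receptor. The 3 gene lists concerned were called higher by camera, and these calls were lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.182, 0.441 and 0.529 for the pteridine, melanin and melanocortin lists). Over all genes, 1 of 37, 0 of 72 and 1 of 23 members passed. Gch1 (gene 110502330), GTP cyclohydrolase 1, which catalyses the entry step of pteridine synthesis, rose from 13 ± 0.556 FPKM in wild-type to 55.2 ± 9.57 FPKM in yellow mutant skin (SD, n = 3 each), a 4.24-fold difference of means. mc5ra (gene 110496762), a melanocortin receptor, rose from 1.47 ± 0.137 to 6.27 ± 0.852 FPKM, or 4.26-fold. Melanin genes that rose when adjusted over their list alone, but did not pass over all genes, included tyrosinase (tyr, gene 100135828), at 9.15 ± 0.983 in wild-type and 21.1 ± 5.85 FPKM in yellow mutant skin. Endothelial, cell cycle, heat shock and collagen gene lists were lower as groups in yellow mutant skin by camera. With an estimated correlation these calls were lost (camera, Benjamini-Hochberg adjusted p = 0.529, 0.682, 0.496 and 0.529), and without wild-type replicate 1 the cell cycle call was lost too (0.204).

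Of 27268 genes tested, 9 rose and 0 fell in yellow mutant skin (limma, Benjamini-Hochberg adjusted over all genes). All 9 are protein-coding genes, as were 26902 of the genes tested, while the other 366 had no class, so noncoding genes were not tested as a class. The 9 genes had every yellow mutant sample above every wild-type sample, which so small a p at 3 samples against 3 largely sets. Besides Gch1 and mc5ra, cyb561a3 (gene 110522835), an ascorbate-dependent cytochrome b, rose most on the log2 scale, from 0.804 ± 0.452 to 15.6 ± 5.88 FPKM. Its log2 fold change was 3.16 with a standard error of 0.31 (limma, Benjamini-Hochberg adjusted p = 0.0323). The log2 fold change of Gch1 was 1.99 with a standard error of 0.17 and that of mc5ra 1.55 with a standard error of 0.14 (limma, Benjamini-Hochberg adjusted p = 0.0188 for both). S100a4 (gene 110517409), named ictacalcin, a calcium-binding protein, rose from 21.2 ± 0.847 to 87.4 ± 9.0 FPKM (limma, Benjamini-Hochberg adjusted p = 0.0188). plin6 (gene 110486293), perilipin 6, a lipid droplet coat protein, rose from 7.36 ± 0.55 to 24.9 ± 3.66 FPKM (limma, Benjamini-Hochberg adjusted p = 0.0286). slc30a8 (gene 110496805), zinc transporter 8, rose from 0.591 ± 0.0781 to 3.04 ± 0.181 FPKM, and zgc:113142 (gene 110498068) from 0.864 ± 0.484 to 6.86 ± 1.06 FPKM. The remaining genes were the uncharacterized LOC118937719, which rose 5.17-fold, and LOC110486160, which rose 4.16-fold.

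The 5 higher genes with the next smallest p, taken only from genes with no overlap between genotypes, did not pass over all genes (limma, Benjamini-Hochberg adjusted p from 0.0513 to 0.059). prph (gene 110494199), plasticin, an intermediate filament protein, was at 0.415 ± 0.0913 FPKM in wild-type and 5.25 ± 2.15 FPKM in yellow mutant skin. uraha (gene 110506594), an enzyme of urate breakdown, was at 24.7 ± 1.76 and 69.1 ± 8.65 FPKM, and dgat2 (gene 110533663), which completes triglyceride synthesis, at 4.57 ± 0.418 and 11.5 ± 1.16 FPKM. Tmem130 (gene 110503068) and si:dkey-73n8.3 (gene 110535416) had log2 fold changes of 1.62 and 1.43. Over all libraries 0 genes were called lower (707 at an unadjusted p under 0.05), and the 12 lowest p-values among named lower genes had adjusted values of 0.0551 to 0.26 (limma, Benjamini-Hochberg). NFATC1 (gene 110518416), a transcription factor, led them with 24.0 ± 1.51 FPKM in wild-type and 8.60 ± 1.32 FPKM in yellow mutant skin. It was called lower with the 5 FPKM filter, with median-of-ratios scaling and without trend or robust (limma, Benjamini-Hochberg adjusted p = 0.0358, 0.0496 and 0.0465). g0s2 (gene 110532623), an inhibitor of triglyceride breakdown, was at 121 ± 21.0 and 51.1 ± 1.48 FPKM, and cd209 (gene 100136662), a lectin of immune cells, at 17.1 ± 0.90 and 7.83 ± 1.13 FPKM. The log2 fold changes of the others were -2.16 for Ccnt2 (gene 110501869), -1.54 for CNN1 (gene 110486482), -1.47 for als2a (gene 110501974), -1.07 for Ehd2 (gene 110508136) and -0.99 for Slc5a6 (gene 110522277). They were -0.94 for osgep (gene 110490645), -0.85 for CYP2J2 (gene 110530539), -0.81 for SYT7 (gene 110513838) and -0.78 for C20orf27 (gene 118941386).

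The pteridine and xanthophore list, which covers the pigment chemistry and cell markers of yellow pigment cells, was higher in yellow mutant skin (37 genes, median log2 fold change 0.09, camera, Benjamini-Hochberg adjusted p = 2.32e-05). This call was lost at adjusted p = 0.182 with an estimated correlation (camera, Benjamini-Hochberg). The median was 0.03 without yellow mutant replicate 1, 0.21 without wild-type replicate 1 or yellow mutant replicate 2, and 0.24 with log2 relative depth as a covariate. Adjusted over the list alone, 12 members rose, 0 fell and 25 did not pass, while 1, Gch1, passed over all genes (limma, Benjamini-Hochberg). Among them pts (gene 110498891), the enzyme that acts after Gch1, was at 3.43 ± 0.579 and 11.0 ± 2.70 FPKM. The xanthophore transcription factor genes pax7b (gene 100884157) and pax7a (gene 100884158) differed 2.96-fold and 2.43-fold, and csf1r1 (gene 110504828), a receptor of xanthophores and macrophages that is also in the melanocortin and macrophage lists, 1.69-fold. The remaining risers were pairs of AKR1B1 and SLC2A11 copies, slc2a15a, SLC2A9 and Pcbd2. fry gave this list a directional p of 4.12e-04, and it was the 1 list of 30 that passed fry's directional test after Benjamini-Hochberg adjustment. In fry's mixed test, which takes changes in either direction, 6 lists passed after that adjustment, those of pteridine, melanocortin, melanin, carotenoid, adipocyte and purine genes.

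The melanin and melanosome list was higher in yellow mutant skin (72 genes, median 0.26, camera, Benjamini-Hochberg adjusted p = 1.36e-14, with adjusted p = 0.441 with an estimated correlation). Adjusted over the list alone, 16 members rose, 0 fell and 56 did not pass (limma, Benjamini-Hochberg), and 0 passed over all genes, although 28 had an unadjusted p under 0.05. The melanosome protein genes PMEL (gene 110528226) and mlana (gene 110523960) were at 95.7 ± 8.11 and 38.7 ± 1.71 FPKM in wild-type and at 164 ± 38.5 and 66.2 ± 4.28 FPKM in yellow mutant skin. mitfa (gene 110494592), the master regulator of melanocytes, was at 2.29 ± 0.45 and 5.08 ± 0.422 FPKM, and tspan36 (gene 110525244), a tetraspanin, at 12 ± 0.777 and 37.5 ± 9.90 FPKM. The other risers were tyr (gene 100135828), DCT (gene 110501902), SOX10, EDNRB, slc24a5, GPR143, Myo5a, MITF (gene 110527878) and pairs of Rab38 and MLPH copies. The melanocortin and pigment hormone list was higher too (23 genes, median 0.24, camera, Benjamini-Hochberg adjusted p = 1.69e-04, with adjusted p = 0.529 with an estimated correlation). Its median was 0.10 without wild-type replicate 1, 0.16 without wild-type replicate 2 or yellow mutant replicate 2, 0.40 without wild-type replicate 3 and 0.11 with log2 relative depth as a covariate. In the list mc5ra and csf1r1 rose, adjusted over the list alone, and 21 members did not pass (limma, Benjamini-Hochberg). Lists of other cell types moved in the same samples, with medians of 0.21 for keratinocyte, 0.32 for mucous and club cell and -0.34 for endothelial genes.

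**Figure D1:**
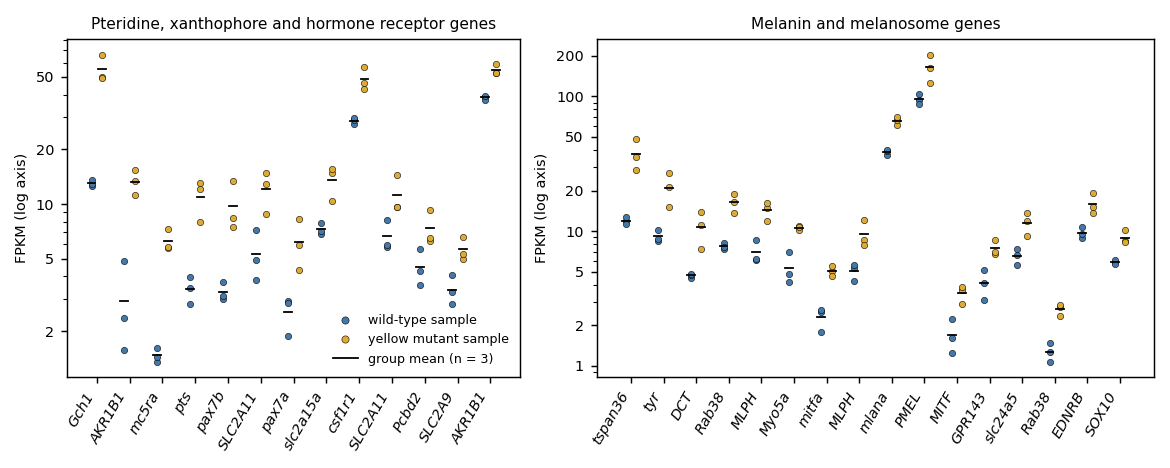
FPKM on log axes of each wild-type and yellow mutant sample, with group means (n = 3), for the 29 genes of the 3 pigment lists that passed when adjusted over the list alone. In all 29 genes every yellow mutant sample lies above every wild-type sample, and the log2 fold changes run from 0.49 to 1.99. The genes were drawn for a small p, so the lack of overlap is largely set by that choice.

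Of 28 copies of classical pigment genes in the table, 15 were tested and 13 lay below the filter on low values, and values of single copies are uncertain where copies share reads. Of the 15, 10 were higher in yellow mutant skin, 7 had an unadjusted p under 0.05, all higher, and 0 passed over all genes (limma, Benjamini-Hochberg). These 7 were mitfa, tyr (gene 100135828), DCT (genes 110501902 and 110520165), PMEL (genes 110528226 and 110494197) and slc45a2, a melanosome transporter gene at 3.97 ± 0.588 and 7.65 ± 3.3 FPKM. tyrp1 (gene 110500604), a melanin enzyme gene, was at 138 ± 6.96 and 198 ± 46.9 FPKM, with a log2 fold change of 0.49. DCT (gene 110520165) was low in wild-type, at 0.182 ± 0.101 FPKM, and most of its yellow mutant mean of 2.63 ± 2.79 FPKM came from replicate 3, at 5.85 FPKM. PMEL (gene 110494197), whose product name is protein QNR-71-like, had a log2 fold change of 0.98 and tyr (gene 100135825) of 0.34. The most abundant DCT copy (gene 110520164) was at 61.4 ± 9.14 and 53.9 ± 14.7 FPKM. oca2, which is needed for melanin, was at 10.5 ± 0.287 and 10.7 ± 4.23 FPKM, with a 95% interval of the log2 difference from -0.66 to 0.58. The log2 fold changes of the melanocortin receptor genes MC1R (gene 110506598) and mc1r (gene 100499611) were 0.32 and -0.05, of asip2b (gene 110508992) -0.26 and of the carotenoid-cleaving BCO2 (gene 110534238) -0.03.

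Carotenoid and retinoid genes moved both ways, and the list was not called (74 genes, median -0.03, camera, Benjamini-Hochberg adjusted p = 0.417). Adjusted over the list alone, 5 members rose and 3 fell (limma, Benjamini-Hochberg). The risers were SCARB1 (gene 110523398), a receptor through which carotenoids enter cells, at 13.3 ± 1.43 and 24.6 ± 6.88 FPKM, a pair of ttc39b copies (genes 110497341 and 110497330) at 3.25-fold and 2.41-fold, rdh3 (gene 100305177) and ALDH1A3 (gene 110506179). CYP2J2, SCARB2 (gene 110523977) and PLIN2 (gene 110500648) fell by 0.85, 0.99 and 0.81 on the log2 scale. In the adipocyte and lipid storage list, plin6, dgat2, fabp4b (gene 110505566) and Pnpla2 (gene 110490314) rose, adjusted over the list alone. Its median was nevertheless -0.12 over 49 genes (-0.23 without yellow mutant replicate 1), and it was not called (camera, Benjamini-Hochberg adjusted p = 0.0687). The purine and iridophore list was not called either (49 genes, median 0.07, camera, Benjamini-Hochberg adjusted p = 0.089), and in it pnp6 (gene 110520537), a purine nucleoside phosphorylase, rose from 0.194 ± 0.157 to 1.71 ± 0.17 FPKM, adjusted over the list alone.

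Gene lists of the skin surface were called higher in yellow mutant skin by camera, and 0 of these calls held with an estimated correlation. In the keratinocyte list 60 of 73 genes were higher (median 0.21, camera, Benjamini-Hochberg adjusted p = 3.55e-05, with adjusted p = 0.632 with an estimated correlation). In the mucous and club cell list 75 of 84 genes were higher (median 0.32, camera, Benjamini-Hochberg adjusted p = 1.39e-06, with adjusted p = 0.642 with an estimated correlation). No member of either list passed, even over the list alone. The smallest p belonged to krt18 (gene 110536988), a keratin, at 0.899 ± 0.302 and 3.81 ± 2.46 FPKM, and to si:ch1073-15f19.2 (gene 110510290), a mucin-5AC gene, at 2.39 ± 0.324 and 4.02 ± 0.403 FPKM. The mucous and club cell call was lost without yellow mutant replicate 2 and with log2 relative depth as a covariate (camera, Benjamini-Hochberg adjusted p = 0.055 and 0.75). Its median was 0.04 without wild-type replicate 1, 0.58 without wild-type replicate 3, 0.50 and 0.19 without yellow mutant replicates 1 and 2 and 0.02 with the covariate, and that of the keratinocyte list was 0.14 and 0.42 without wild-type replicates 1 and 3. The cytosolic ribosomal protein list was higher in 170 of 184 genes (median 0.18, camera, Benjamini-Hochberg adjusted p = 4.33e-09, with adjusted p = 0.537 with an estimated correlation), and after quantile normalization its median was 0.06, with 129 genes higher. In it rpsa, an assembled transcript, was at 1.56 ± 0.619 and 4.60 ± 1.13 FPKM. The T and NK lymphocyte list was higher in 22 of 27 genes (median 0.24, camera, Benjamini-Hochberg adjusted p = 0.0033, with adjusted p = 0.537 with an estimated correlation), led by cd3e (gene 100499597) at 3.45 ± 0.725 and 5.19 ± 0.623 FPKM. Without yellow mutant replicate 2 and with the depth covariate this call was lost (camera, Benjamini-Hochberg adjusted p = 0.189 and 0.296), at medians of 0.14 and 0.11.

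Lists of vessels, connective tissue and dividing cells were called lower in yellow mutant skin by camera, again with 0 calls under an estimated correlation. In the endothelial and vascular list 40 of 46 genes were lower (median -0.34, camera, Benjamini-Hochberg adjusted p = 4.33e-09, with adjusted p = 0.529 with an estimated correlation). Its 1 member past the threshold over the list alone, CNN1, the smooth muscle protein calponin-1, fell from 11.1 ± 4.12 to 2.97 ± 0.383 FPKM. In the cell cycle list 64 of 68 genes were lower (median -0.30, camera, Benjamini-Hochberg adjusted p = 2.07e-08, with adjusted p = 0.682 with an estimated correlation), with bub1 (gene 110529487), a mitotic checkpoint kinase, at 1.18 ± 0.461 and 0.566 ± 0.156 FPKM. Without wild-type replicate 1 and with log2 relative depth as a covariate this call was lost (camera, Benjamini-Hochberg adjusted p = 0.204 and 0.0683), at medians of -0.08 and -0.11. In the heat shock and early stress list 83 of 115 genes were lower (median -0.21, camera, Benjamini-Hochberg adjusted p = 3.06e-08, with adjusted p = 0.496 with an estimated correlation), with JUND (gene 110530134) at 13.8 ± 3.64 and 6.93 ± 0.336 FPKM. In the dermal fibroblast and collagen list 104 of 152 genes were lower (median -0.16, camera, Benjamini-Hochberg adjusted p = 1.66e-04, with adjusted p = 0.529 with an estimated correlation), with COL6A3 (gene 110519978) at 652 ± 35.9 and 385 ± 71.1 FPKM. The endothelial median was -0.20 without wild-type replicate 2, -0.23 without yellow mutant replicate 2 and -0.18 with the covariate, the collagen median -0.10 without yellow mutant replicate 3, and the cell cycle median -0.56 without wild-type replicate 3 and -0.52 and -0.15 without yellow mutant replicates 1 and 3.

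In the erythrocyte list 28 of 31 genes were lower (median -0.36, camera, Benjamini-Hochberg adjusted p = 3.18e-04, with adjusted p = 0.682 with an estimated correlation). Its member with the smallest p, the haemoglobin gene zgc:163057 (gene 100301693), was at 0.791 ± 0.335 and 0.357 ± 0.342 FPKM. The call was lost without wild-type replicate 1 and without wild-type replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.172 and 0.205), at medians of -0.12 and -0.10, and the median was -0.82 without wild-type replicate 3. The fatty acid oxidation list was lower in 27 of 41 genes (median -0.09, camera, Benjamini-Hochberg adjusted p = 0.00676, with adjusted p = 0.682 with an estimated correlation), with PPARA (gene 110521393), a regulator of that pathway, at 12.1 ± 2.35 and 7.04 ± 2.2 FPKM. That call was lost without wild-type replicate 1, without yellow mutant replicate 2 and with log2 relative depth as a covariate (camera, Benjamini-Hochberg adjusted p = 0.128, 0.44 and 0.969), at medians of -0.04, -0.00 and -0.02, and the median was -0.05 without wild-type replicate 2 and -0.14 without yellow mutant replicate 1.

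The other lists were not called by camera, all with Benjamini-Hochberg adjustment. The scale and bone forming list (29 genes) had a median of 0.16 and an adjusted p of 0.141 (camera, Benjamini-Hochberg), and the skeletal muscle list (170 genes) 0.14 and 0.089. The skeletal muscle median ran from -0.11 without yellow mutant replicate 2 to 0.40 without yellow mutant replicate 3. For immune cells, the median and adjusted p were 0.11 and 0.0687 for macrophage and granulocyte genes, 0.09 and 0.274 for B lymphocyte genes, and 0.06 and 0.141 for interferon response genes (camera, Benjamini-Hochberg). For metabolism they were -0.05 and 0.0687 for nuclear oxidative phosphorylation genes, -0.07 and 0.627 for mitochondrially encoded genes, 0.03 and 0.634 for glycolysis and -0.01 and 0.456 for cholesterol synthesis (camera, Benjamini-Hochberg). They were 0.07 and 0.417 for glutathione and antioxidant genes, 0.05 and 0.148 for the proteasome and 0.07 and 0.417 for the circadian clock (camera, Benjamini-Hochberg). The Wnt pathway list had a median of -0.02 and an adjusted p of 0.81, and the neural crest and Schwann cell list -0.01 and 0.813 (camera, Benjamini-Hochberg). Of the list members with the smallest p, GSTK1 (gene 110509171), a glutathione transferase, was at 15.8 ± 3.98 and 6.85 ± 0.358 FPKM, and hlfb (gene 110502767), a clock-controlled transcription factor, at 6.63 ± 1.30 and 12.1 ± 2.31 FPKM. gapdh (gene 110496191) was at 263 ± 29.0 and 419 ± 95.8 FPKM, NEB (gene 110520260) at 3.67 ± 0.262 and 6.01 ± 1.28 FPKM, and FRZB (gene 110520325), a secreted Wnt antagonist, at 26.8 ± 5.62 and 17.0 ± 3.32 FPKM. The log2 fold changes of the other such members were 0.68 for the Ig lambda gene LOC110498416, 0.56 for TRIM25 (gene 110531528, whose product name is TRIM7), -0.51 for insig1 (gene 110535597), -0.62 for Ndufa4l2 (gene 110492353), -0.37 for PSMD11 (gene 110521930) and -0.28 for ND3.

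**Figure D2:**
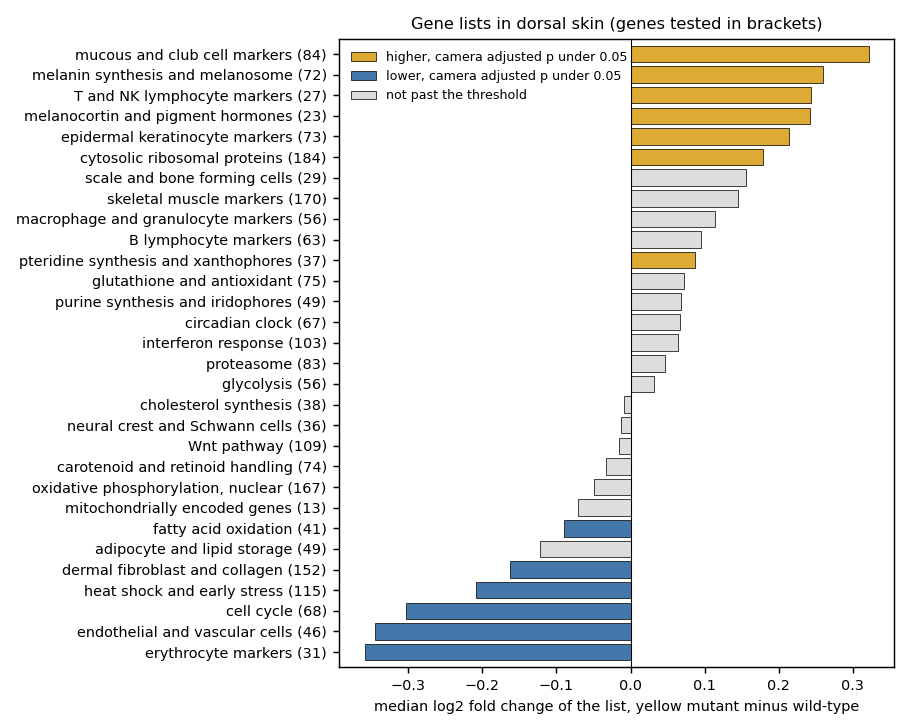
Median log2 fold change (yellow mutant minus wild-type, on the log2(FPKM + 1) scale) of each of the 30 gene lists, with the number of genes tested in brackets. The 7 yellow bars and 6 blue bars mark lists past an adjusted p of 0.05 by camera with the preset correlation, and 0 lists passed with an estimated correlation.

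With camera's preset correlation 13 of 30 gene lists were called, 7 higher and 6 lower, and with an estimated correlation 0 were (2 at an unadjusted p under 0.05), while fry gave 5 lists a directional p under 0.05. At an unadjusted p under 0.05 limma gave 930 genes higher and 707 lower (858 and 803 after median-of-ratios scaling, 857 and 814 after quantile normalization), and 2998 genes (11.0%, where chance gives 10%) had no overlap between genotypes, of which 1656 were higher in yellow mutant skin. The authors' deposited table gives 138 genes an FDR under 0.05, 97 higher and 41 lower in yellow mutant skin. Of these genes in the authors' deposited table, 132 were tested here, 132 had the same sign, 131 had a limma p under 0.05 and 9 were called. In the authors' deposited table, 19 of the 138 genes belong to the 3 pigment lists. The 9 limma calls depend on single libraries, since 0 genes were called without wild-type replicate 1, wild-type replicate 3 or yellow mutant replicate 3, and 1, not among the 9, without wild-type replicate 2. Without yellow mutant replicate 1 limma called 12 genes and without yellow mutant replicate 2 it called 14, each with 6 of the 9 among them. Of these calls 2 and 4 were lower in yellow mutant skin, those of ncam3 and ck073, and of Uqcrh, ltn1, Samd4b and LOC110518414. The log2 fold changes of the 9 genes stayed between 1.30 and 3.5 with each library left out. With log2 relative depth as a covariate, chosen after the data were seen, 0 genes passed (2043 at an unadjusted p under 0.05), while the log2 fold changes of the 9 genes were 1.35 to 3.47 with it and 1.34 to 3.16 without it, and the degrees of freedom of the moderated test, prior plus residual, dropped from at most 7.89 to at most 6.57.

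Wild-type replicate 1 stood apart in liver transcripts, which were chosen after their values were seen. Of 97 measured copies of 46 liver gene symbols, 88 (90.7%, where chance gives 16.7%) were highest in that library. The albumin gene alb1 (gene 100499622) was at 377 FPKM there and at 23.7 to 34.9 FPKM in the other 5 libraries. In the miRNA assay miR-122-x, of the miRNA family that dominates liver, was at 1094 RPM in wild-type replicate 1 and at 71.4 to 162 in the other 5 libraries. Of the 97 copies, 3 belong to a gene list tested here.

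**Figure D3:**
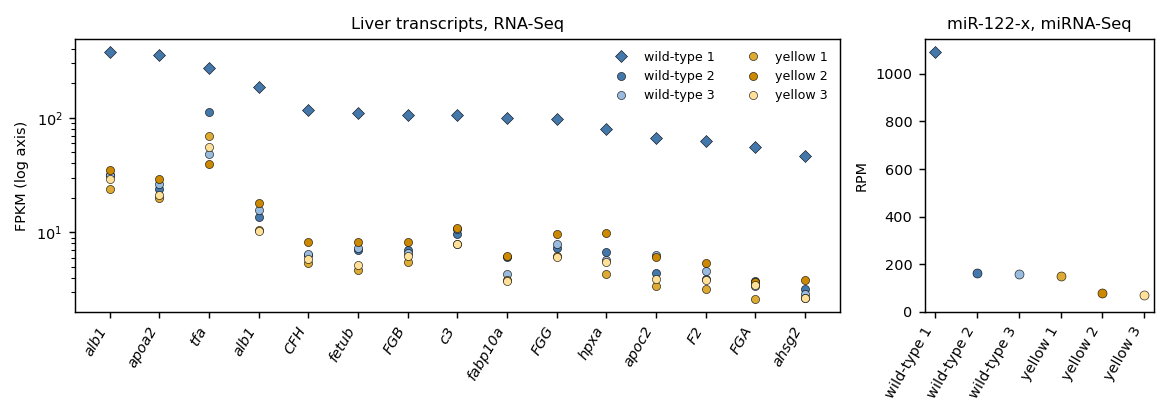
FPKM on a log axis of 15 liver transcripts and RPM of miR-122-x in each of the 6 libraries of each assay. The transcripts drawn were picked for a high level and a large excess in wild-type replicate 1 (diamond). That it lies highest in them is therefore set by the choice. In that library alb1 (gene 100499622) was at 377 FPKM and miR-122-x at 1094 RPM.

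The second comparison asks which miRNAs differ between the 2 skins. Epithelial miRNA families were higher in yellow mutant skin as a group by camera, and no single miRNA passed the test. The call was lost with an estimated correlation, without wild-type replicate 1 and without yellow mutant replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.731, 0.062 and 0.186), and its median was 0.24 and 0.33 without those libraries. miR-205-x, of a family abundant in surface epithelia, was at 9713 ± 2202 RPM in wild-type and 17969 ± 8042 in yellow mutant skin (SD, n = 3 each), or 1.85-fold. miR-204-y, of a family known from pigmented cells, was at 37.1 ± 8.19 and 70.4 ± 16.4 RPM, or 1.89-fold, while the abundant miR-204-x and miR-211-z were nearly flat, each at 1.09-fold. miR-204-x and miR-211-z tracked each other across libraries, at 9100 and 8164 RPM in wild-type replicate 1 and 16076 and 14788 in wild-type replicate 3. They may therefore not be separate signals. The miRNA reads were dominated by miR-199-x, which took 45.8 to 58.1% of the denominator of each library and had a log2 fold change of -0.05.

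Of 519 miRNA entries tested, limma called 0 (lowest Benjamini-Hochberg adjusted p 0.212), with 31 higher and 12 lower at an unadjusted p under 0.05 (23 and 16 after median-of-ratios scaling). voom on the recovered reads called 0 as well, with 39 at an unadjusted p under 0.05. The groups did not overlap for 53 entries (10.2%, where chance gives 10%). Median-of-ratios scaling moved the median log2 fold change of the 519 entries from 0.10 to 0.02, and the changes given here are without it. Among higher entries with the smallest p, the log2 fold changes were 0.84 for miR-205-z, 0.92 for miR-725-x, 0.97 for miR-1788-y, 0.86 for miR-196-y and 0.70 for miR-199-z, and the predicted miRNA m0012-5p was at 14.2 ± 3.57 and 40.5 ± 28.0 RPM. Among lower entries, miR-122-x, with its level of 1094 RPM in wild-type replicate 1, had a log2 fold change of -1.67. That value leans on this library, since miR-122-x was at 162 and 158 RPM in wild-type replicates 2 and 3. In yellow mutant replicates 1, 2 and 3 it was at 150, 79.7 and 71.4 RPM. The predicted miRNA m0033-3p was at 11.4 ± 2.17 RPM in wild-type skin and had 0 reads in yellow mutant replicates 1 and 3 but 9.90 RPM in replicate 2. The log2 fold changes of the other lower entries were -0.44 for miR-27-x, -0.36 for miR-722-y, -0.34 for miR-139-x, -0.36 for miR-145-y, and -0.87 and -0.47 for the predicted m0034-5p and m0010-3p.

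In the epithelial family list all 18 tested members were higher in yellow mutant skin (17 after median-of-ratios scaling, where miR-24-y turned lower), with a median log2 fold change of 0.58. camera called this list (Benjamini-Hochberg adjusted p = 0.00176, and adjusted p = 0.731 with an estimated correlation), and 0 members passed over the list alone. Its members include miR-200-y at 5074 ± 1782 and 7668 ± 2130 RPM, miR-203-y at 943 ± 469 and 1562 ± 739, and miR-184-y at 1569 ± 899 and 2329 ± 1337.

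**Figure D4:**
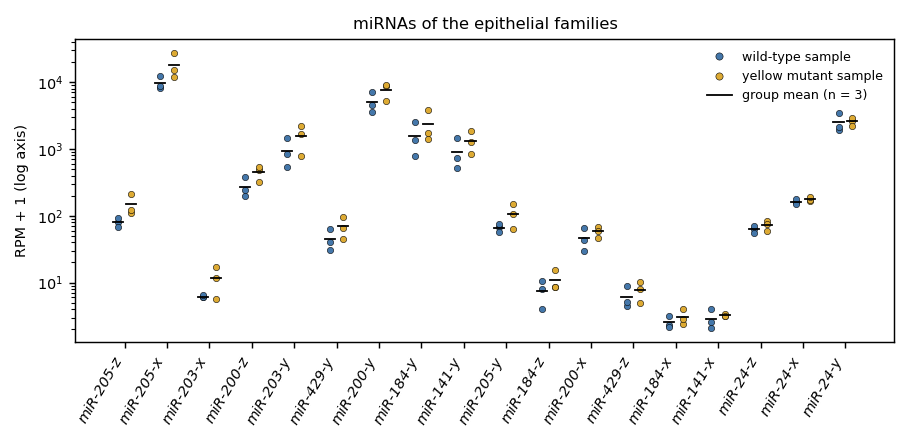
RPM + 1 on a log axis of the 18 epithelial miRNA entries in each wild-type and yellow mutant sample, with group means (n = 3). All 18 means on the log2 scale are higher in yellow mutant skin, with a median log2 fold change of 0.58, although samples of the genotypes overlap in most entries and miR-24-y turns lower after median-of-ratios scaling.

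The other family lists were not called. The median log2 fold change was 0.43 over 9 skeletal muscle entries (camera, Benjamini-Hochberg adjusted p = 0.201), with miR-206-y at 566 ± 243 and 788 ± 405 RPM. With 1 library left out that median ran from 0.16 (without wild-type replicate 2) to 0.72 (without wild-type replicate 3). The list passed without wild-type replicate 1 and without yellow mutant replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.0207 and 0.00214). The median was 0.22 over 10 entries of the miR-17-92 cluster (camera, Benjamini-Hochberg adjusted p = 0.424), with miR-92-y at 2876 ± 264 and 3073 ± 306. The other 5 lists had an adjusted p of 0.525 (camera, Benjamini-Hochberg). Among these, the melanocyte and pigment list (26 entries) had a median of 0.10 that turned to -0.01 after median-of-ratios scaling, with its most abundant entry miR-27-y at 25473 ± 5368 and 25575 ± 2419 RPM. The blood cell list had a median of 0.17, with miR-181-x at 0.19, and the nerve list 0.18, with miR-128-y at 0.35. The fibroblast and vessel list had a median of -0.01 and a mean of 0.04, and its test pointed lower, while the let-7 list had a median of -0.06, with let-7-x at -0.07. In the authors' deposited table, 65 miRNA entries had a p-value under 0.05, and of the 33 of these tested here 28 had a limma p under 0.05.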

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

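The tests of epidermis share, of liver RNA (in the liver and pigment patterns) and with the depth covariate were chosen after the results were seen.

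Entries named after the miR-506 family, left out by the filter on low values, had reads in yellow mutant replicates 2 and 3 and in 0 wild-type libraries. They were miR-514-y with 111 reads in all, miR-506-y with 28, miR-509-y with 18, miR-508-y with 15 and miR-509-x with 14. A predicted miRNA entry, also below the filter, had 9 reads, 5 in yellow mutant replicate 1 and 4 in replicate 3, and 0 in wild-type libraries. Each total lies above the 3 reads that a count of 0 allows.

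The first pattern weighed is that of the 5 miR-506 family names, with 84 reads in yellow mutant replicate 2, 102 in replicate 3 and 0 in the other 4 libraries. Carry-over from another library or organism stays open, since 0 names outside the family were seen at 5 or more reads in those libraries and at 0 in the other 4, and shared sequences would hide such reads. No biological explanation was tested, and yellow mutant replicate 1 also held 0 reads of the family.

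The next pattern is the higher level of the 3 pigment gene lists in yellow mutant skin, with a median log2 fold change of 0.22 over all 126 tested members. Unequal depth and liver RNA in wild-type replicate 1 are argued against as the whole cause for the melanin list. Its median of 0.26 was 0.30 with log2 relative depth as a covariate and 0.22 without that library. The pteridine median went from 0.09 to 0.24 and 0.21 in those fits. It was also 0.03 without yellow mutant replicate 1, too unsteady to decide. Depth goes partly with genotype, at 0.582 and 0.812 in yellow mutant replicates 2 and 3, so the covariate cannot fully separate them. Together the 109 members of both lists had a median of 0.21, of 0.27 with the covariate and of 0.21 without wild-type replicate 1. Both lists passed with the covariate (camera at the preset correlation, Benjamini-Hochberg adjusted p = 1.36e-13 and 1.19e-05) and without the library (2.16e-10 and 1.04e-06), although neither passed with an estimated correlation over all libraries (0.441 and 0.182). At the preset correlation another split of the libraries called 21 lists, so passing cannot decide by itself, and the argument rests on the melanin medians. An estimated correlation was not used with the covariate or without the library. For the pteridine list both explanations stay open. They do so for the melanocortin list too, since its median of 0.24 went to 0.11 and 0.10 in those fits. A larger share of epidermis stays open for all 3 lists, since the keratinocyte list had a median of 0.21. More pigment cells, or more transcript per pigment cell, in the yellow mutant genotype may explain the pattern and stays an untested hypothesis.

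The last pattern is the high level of liver transcripts in wild-type replicate 1, where 90.7% of 97 liver gene copies were highest, with a median excess of 5.49-fold on the log2(FPKM + 1) scale. Liver tissue or liver RNA in that sample is a candidate explanation, and miR-122-x at 1094 RPM in the same-numbered miRNA library goes with it, although 56 of the copies also had a mean of at least 1 FPKM in the other libraries. More blood in the sample stays open, since the erythrocyte list had a median log2 excess of 0.79 there against 2.46 for the liver list, between the bounds set for the test. No biological explanation by genotype was tested, since the pattern lies in 1 library.

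Splits of the 6 libraries, 3 against 3, number 10, too few for a share under 0.05. The counts that follow include the real split itself and take splits with as many calls or more. For called genes, 2 of the 10 splits gave as many as the real 9, and the highest other gave 15. That split sets wild-type replicates 1 and 2 with yellow mutant replicate 1, the 3 libraries of greatest estimated depth, against the rest, with 3420 genes at an unadjusted p under 0.05, so the samples hold a structure other than genotype. With log2 relative depth as a covariate 0 genes passed by limma (2043 at an unadjusted p under 0.05). For called gene lists, 5 of 10 splits gave as many as the real 13, and the highest other gave 21. For called miRNAs the real count was 0, as in all 10 splits, and the highest other was 0. For called miRNA family lists, 6 of 10 splits gave as many as the real 1, and the highest other gave 3.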

How the results depend on the processing

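Chosen after the data were seen were the depth covariate, 1 entry per distinct sequence, voom on recovered reads, the block with an estimated correlation and, for miRNA family lists, the other pseudocount and scaling. The count of 9 called genes stayed between 6 and 13 with other pseudocounts, filters, scalings, a fold threshold and without trend or robust. It was 0 with log2 relative depth as a covariate, which takes up a degree of freedom and left log2 fold changes of 1.35 to 3.47, and 140 at an unadjusted p under 0.05 with an absolute log2 fold change of at least 1, which drops the adjustment and adds a fold threshold (1637 without the latter). With 1 library left out it ranged from 0 to 14, where fewer samples are part of the cause. Without wild-type replicate 2 it was 1, Btn2a2. The count of called miRNAs was 10 at an unadjusted p under 0.05 with an absolute log2 fold change of at least 1, and ranged from 0 to 2 with 1 library left out. It was 2 without wild-type replicate 1 (predicted m0135-5p and m0136-5p), 1 without wild-type replicate 3 (predicted m0059-5p), and 1 without yellow mutant replicate 2 (predicted m0033-3p). Elsewhere it stayed at 0 (limma and voom).

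Of 30 gene lists, 13 were called, 0 with an estimated correlation, and 11 to 19 with 1 library left out. Of 8 miRNA family lists, 1 was called, 0 with an estimated correlation, and 0 to 2 with 1 library left out (0 without yellow mutant replicate 2, 2 without yellow mutant replicate 3). Only camera's correlation setting was changed for the estimated correlation, and what in it caused those losses was not tested. Of the 13 gene list calls, 8 held in all 6 fits that left out a library. With the depth covariate 12 lists were called, and the mucous and club cell, T and NK lymphocyte, fatty acid oxidation and cell cycle calls were lost (camera, Benjamini-Hochberg adjusted p = 0.75, 0.296, 0.969 and 0.0683). Calls gained were mitochondrially encoded genes, lower, and the proteasome and purine lists, higher (camera, Benjamini-Hochberg adjusted p = 7.44e-12, 4.08e-04 and 0.0161). The cause was not tested for these.

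Same-numbered samples do not pair. The correlations of their deviations from the group means were 0.116, -0.213 and 0.158 for RNA-Seq and 0.0883, -0.121 and -0.0585 for miRNA-Seq, and not every sample correlated best with its own number. With the replicate block 0 genes were called by limma (1795 at an unadjusted p under 0.05) and 0 miRNAs (40), 15 gene lists and 1 family list passed by camera, and the replicate block with an estimated correlation called 0 of either.

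Some lists changed direction when 1 library was left out. Their adjusted p (camera, Benjamini-Hochberg), lowest to highest over those 6 fits, was 0.534 to 0.896 for the Wnt pathway, 0.147 to 0.9 for carotenoid, 0.157 to 0.953 for cholesterol, 0.0971 to 0.936 for circadian clock, 0.0288 to 0.699 for glutathione, 0.0188 to 0.801 for glycolysis, 3.37e-05 to 0.901 for mitochondrially encoded, 0.0686 to 0.956 for neural crest, 1.67e-04 to 0.863 for oxidative phosphorylation, 5.68e-05 to 0.692 for proteasome and 2.86e-05 to 0.165 for skeletal muscle genes. For family lists it was 0.311 to 0.9 for blood cell and 0.314 to 0.9 for melanocyte families. The lowest values came without wild-type replicate 1 (glutathione, proteasome), wild-type replicate 3 (oxidative phosphorylation), yellow mutant replicate 2 (mitochondrially encoded) and yellow mutant replicate 3 (glycolysis, skeletal muscle). Other lists that crossed the threshold reached 0.0188 (adipocyte, without yellow mutant replicate 3), 0.0307 (interferon, without wild-type replicate 3), 0.0403 (macrophage, without yellow mutant replicate 3), 0.0242 (purine, without wild-type replicate 3), 5.98e-04 (scale and bone, without wild-type replicate 1) and, for skeletal muscle families, 0.00214 (without yellow mutant replicate 3) at the lowest (camera, Benjamini-Hochberg). The depth covariate turned the carotenoid (0.789), circadian clock (0.225), neural crest (0.0777), oxidative phosphorylation (0.13) and skeletal muscle (0.225) lists, again as adjusted p (camera, Benjamini-Hochberg), and the log2 fold changes of DCT (gene 110520164) to 0.07 and oca2 to 0.27. Quantile normalization turned the glycolysis median to -0.02. The cause was not tested.

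Log2 fold changes that changed sign with 1 library left out ranged from -0.77 to 0.32 for ND3, -0.37 to 0.03 for DCT (gene 110520164), -0.16 to 0.03 for mc1r (gene 100499611), -0.13 to 0.10 for BCO2 and -0.28 to 0.28 for oca2. For miRNAs they ranged from -0.07 to 0.19 for miR-27-y, -0.15 to 0.02 for miR-199-x and -0.25 to 0.10 for let-7-x. Median-of-ratios scaling turned miR-27-y to -0.09 and miR-92-y (0.04 to 0.18 with 1 library left out) to -0.02. The count model on miRNA reads was planned for raw counts only. It was not run, because the values are scaled and entries without reads hold a placeholder, and voom on the recovered reads was run instead. The seed-site test and its alternatives were not run, because no transcript sequences were at hand. The absolute RNA-Seq depth is unknown, and 3 reads limit what a miRNA entry at 0 allows.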

Other observations

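In some transcripts, all chosen after their values were seen, 1 wild-type sample stood apart from the other 2. Btn2a2, a butyrophilin gene, was at 4.48 and 5.14 FPKM in wild-type replicates 1 and 3, and at 83.0 FPKM in wild-type replicate 2, close to 71.4, 67.3 and 60.8 FPKM in the yellow mutant replicates. The predicted miRNAs m0135-5p and m0136-5p, which have equal values, were at 12.2 and 9.32 RPM in wild-type replicates 2 and 3, and at 0.769 in wild-type replicate 1 and 0.956 to 1.13 in yellow mutant skin. The predicted m0059-5p was at 0 and 0.218 RPM in wild-type replicates 1 and 2, at 6.28 in wild-type replicate 3, and at 4.51 to 7.32 in yellow mutant skin.

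vtg3 (gene 110521946), a vitellogenin, or yolk protein, gene, was chosen after its values were seen. It was at 0.564, 2.07 and 1.80 FPKM in wild-type replicates 1, 2 and 3, and at 0.025, 0.044 and 0.016 FPKM in the yellow mutant replicates. Its log2 fold change of -1.21 did not pass over all genes (limma, Benjamini-Hochberg adjusted p = 0.337). Among wild-type samples it was lowest in replicate 1, the library highest in liver transcripts, so it did not follow them. Sex and maturity of the fish were not among the terms tested. In the libraries other than wild-type replicate 1, liver transcripts stood at a median of 7.19 to 10.5% of their level in that library, over all 97 copies.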
